A study of Homo sapiens with 12 samples.

How the data were processed

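Gene expression was measured by RNA sequencing of total RNA (ScriptSeq Complete Gold kit, Illumina, per the labels) in 12 libraries of human pulmonary arterial endothelial cells. Each of 4 groups held 3 libraries: doxorubicin (Dox, 0.5 µg/ml), its vehicle phosphate-buffered saline (PBS, 20 µL), Nutlin-3 (Nutlin, 10 µM) and its vehicle dimethyl sulfoxide (DMSO, 10 µL), all after 24 h. Replicates 1, 2 and 3 were passages 3, 4 and 5, per the labels. The number of donors was not given in the sources used here, so each p-value measures the spread between cultures at different passages.

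The submitters' processing notes name BWA, DESeq2 and edgeR without versions or roles, and the builds hg19 and GRCh37. Counting settings, strand handling and filters were not stated. The deposited table holds, for 23414 genes, a signal per library that the authors had scaled by 1 factor per library. Its name calls it raw counts, but 100% of the nonzero values in each library were whole multiples of 1 step, within a tolerance of 0.05 of a read, and the steps lay between 0.02822 and 0.1151. Dividing by the step recovered whole reads. The deposited columns summed to between 1450500 and 1544870, above the total that CPM would give, so a read could count for more than 1 gene. A pair of result tables of the authors was also deposited, 1 named for DESeq2 and 1 for edgeR, both for a comparison of baseline with complex. They give, per the file headers, the authors' log2 ratio of each gene with its p-value and false discovery rate, list only genes with a false discovery rate under 0.05, and do not state which libraries form each side.

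Recovered reads over genes ranged from 12925944 to 54744631 per library, and the totals that the steps imply ranged from 8.69 to 35.4 M. Replicate 1 of every group was the deepest. The 10 most abundant genes took 5.26 to 8.8% of the reads. Reads carried no molecular identifiers, so counting error is only part of the error of any value.

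Genes were named from the transcript identifiers and hg19 coordinates of the deposited table, 22728 by a RefSeq table and 335 by a GENCODE table, while 351 had no symbol and 435 shared a symbol with another entry. Genes on chromosome Y, XIST and TSIX (129 entries) were left out before any test, because they could carry information on a person. Of the 23285 genes kept, edgeR's filterByExpr, grouped by treatment, passed 13213.

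The design fixed before the data were examined named an edgeR quasi-likelihood test on counts. Because the deposited values are scaled, the test used instead was limma (eBayes with trend) on log2(CPM + 1), where CPM is the usual library-scaled count of recovered reads after TMM scaling and the pseudocount is 1. All 12 libraries entered 1 fit with 1 mean per group, 8 residual degrees of freedom and no covariate. The 4 contrasts were tested two-sided: Dox against PBS, Nutlin against DMSO, the difference of these responses (Nutlin minus Dox), and DMSO against PBS. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 13213 genes tested. Fold changes are on the log2(CPM + 1) scale, which draws the folds of scarce genes towards 0, and errors of fold changes are limma's standard errors. Means are given in CPM with the SD over 3 libraries.

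Whether the numbers pair the libraries was checked from residuals of the group means. The labels share a passage between groups. The 18 same-numbered pairs correlated at 0.62 to 0.93 across genes, differently numbered pairs at -0.90 to 0.82, and 9 of 12 libraries correlated best with their own number in all 3 other groups. A blocked fit, the same fit with the replicate number as a block (6 residual degrees of freedom), was therefore also run, and its value is given beside list counts that it moves by over 1.5 times and beside calls that it changes.

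The fits were tested on simulated data with known folds for 100 genes per fold among 13213, built on the spread of these libraries. limma recovered 6% of 2-fold and 55% of 4-fold changes and called 0 other genes. With the block it recovered 54% and 90% with 6 other genes. edgeR recovered 5% and 52%, DESeq2 30% and 80%, and voom 5% and 48%. All calls had the right direction (100%), and a blocked DESeq2 fit, which called 20 genes in a comparison without changes, was not used.

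There were 25 gene lists of pathways and cell type markers, fixed before the data were examined, with 688 entries of which 680 matched the table. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 25 lists in each contrast, again with an estimated correlation, and with fry, whose test of direction is meant unless its mixed test is named. A list is said to pass by camera with the preset correlation unless another test is named. For each list, members past the threshold were counted over all genes and adjusted over the list alone. Some lists share members, such as 8 between the NF-kB and secretion lists and 4 between the p53 and apoptosis lists. The overlap of the responses was tested with Fisher's exact test across genes, and gene span was compared with fold change by Spearman's rho across genes. Genes are not independent replicates in either.

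Named genes followed a rule fixed beforehand. For the Dox and Nutlin comparisons it took the 8 largest rises and 8 largest falls among genes past the threshold with a group mean of at least 5 CPM, a proper symbol and the same sign in all 3 same-numbered pairs. From each list past the threshold it took the 3 members with the smallest adjusted p in the list's direction, and from other lists the 2 members with the highest mean CPM as values. CDKN1A, MDM2, GDF15, PPARG, MKI67 and PECAM1 were among the genes always named. The text does not print every gene that the rule names. For the difference it took the 6 largest each way, and for DMSO against PBS the 3 largest each way, of which there were 0. Other genes named were chosen after their values were seen, and this is said where they appear. Of the 119 genes named by the rule, 30 overlap another gene of the table on the opposite strand, and reads of such genes could not be assigned with certainty.

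Alternatives planned beforehand were the replicate block, DESeq2 size factors, DESeq2 and voom fits, no filter, fits of only the groups compared, a minimum log2 fold change of 1, each library left out, and each replicate number left out of all groups. The block and the size factors had been planned for an edgeR fit and were run in the limma fit. Alternatives chosen after seeing the data were edgeR on recovered reads, without and with the block, pseudocounts of 0.25 and 4, the scaling as deposited, list, overlap and p53 target results without replicate 1, 2 or 3 of every group, and the overlap and p53 targets under every other setting that refits all genes. No column of the deposited table was left out. The tools were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.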

Results

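The study profiled total RNA of human pulmonary arterial endothelial cells, the cells that line the arteries of the lung, in 12 sequencing libraries. Cells were exposed for 24 h to doxorubicin, an intercalator and topoisomerase II poison that breaks DNA, or to Nutlin-3, which blocks the binding of p53 to its inhibitor MDM2, or to the vehicle of either drug. Each of the 4 groups had 3 libraries, and the study asked which genes respond to p53, and to its complex with the nuclear receptor PPARγ, under DNA damage or direct p53 activation. Recovered reads over genes in replicates 1, 2 and 3 were 54744631, 18459697 and 13228539 with PBS and 47372063, 15941006 and 22808665 with Dox. They were 50117802, 14888252 and 15615555 with DMSO and 45450539, 18144745 and 12925944 with Nutlin. Levels are CPM, these reads scaled by library total and TMM factor, as mean ± SD of n = 3 libraries, and coordinates are hg19. Fold changes are limma's, on the log2(CPM + 1) scale, with adjusted p over the 13213 genes tested. Replicate 1 stood apart in every group: the Pearson correlation of log levels across genes was 0.882 to 0.941 between replicate 1 and the others and 0.996 to 0.997 between replicates 2 and 3. Along the replicate number lay 76.4% of the within-group sum of squares.

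The first comparison, Dox against PBS, asked what DNA damage does to these cells. p53 target genes rose and genes of the cell cycle fell. TP53I3, a p53-induced oxidoreductase, rose from 66.6 ± 9.27 to 2010 ± 455 CPM, and CDKN1A, which encodes the p21 inhibitor of cyclin-dependent kinases, rose from 157 ± 65.7 to 1590 ± 710. MKI67, a marker of proliferating cells, fell from 524 ± 39.4 to 48.4 ± 36.2 CPM. The endothelial adhesion molecule PECAM1 fell from 913 ± 336 to 338 ± 232 CPM. In all, 2539 genes rose and 2492 fell, of 5031 past the threshold, and 1656 and 1450 of them by at least 2-fold.

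Of 50 p53 activated targets, 43 rose, 0 fell and 7 did not pass; adjusted over the list alone, 44 rose. The median log2 fold change of the list was 2.21 (camera adjusted p = 8.3e-22; adjusted p = 0.23 with an estimated correlation). TP53I3 (NM_004881, chromosome 2, 24300303 to 24308085) rose by a log2 fold change of 4.88 (SE 0.22, adjusted p = 7.4e-07). The death receptor gene FAS (NM_152872, chromosome 10, 90750288 to 90775542) rose from 20.4 ± 2.14 to 174 ± 8.67 CPM, a log2 fold change of 3.03 (SE 0.14, adjusted p = 7.4e-07), and the mitochondrial reductase gene FDXR rose from 23 ± 1.69 to 368 ± 47.6 CPM (adjusted p = 1.4e-06). CDKN1A (NM_001220777, chromosome 6, 36644237 to 36655116) rose by 3.31 (SE 0.48, adjusted p = 5.5e-04), and its reads were 2685 to 4067 in PBS and 32209 to 48749 in Dox libraries. MDM2 (NM_001145339, chromosome 12, 69201952 to 69239324), whose product degrades p53, rose from 803 ± 117 to 2760 ± 665 CPM, by 1.76 (SE 0.30, adjusted p = 0.0015). The stress cytokine gene GDF15 rose from 68.4 ± 29.4 to 890 ± 308 CPM, by 3.72 (adjusted p = 9.8e-05). The span of TP53I3 lies within that of FAM228B.

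Apoptosis regulators rose as a list, 10 of 27 with 0 falling and 17 not passing, and 10 adjusted over the list alone (median 0.57, camera adjusted p = 0.003; adjusted p = 0.32 with an estimated correlation). The BH3-only genes PMAIP1 and BBC3, both also p53 targets, rose from 54.7 ± 4.15 to 473 ± 53.4 CPM and from 12.4 ± 1.74 to 67.5 ± 16.1 CPM.

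Of 35 genes of G2/M and mitosis, 34 fell and 1 rose, with the same counts adjusted over the list alone (median log2 fold change -3.98, camera adjusted p = 4.2e-19; adjusted p = 0.32 with an estimated correlation). The kinetochore gene CENPF (NM_016343, chromosome 1, 214776532 to 214837914) fell from 712 ± 67.3 to 15.6 ± 5.77 CPM (log2 fold change -5.49, SE 0.24, adjusted p = 6.7e-07). NUF2, also of the kinetochore, and the mitotic kinase gene PLK1 had log2 fold changes of -4.63 and -4.69. The gene that rose, PTTG1 (securin, named after its value was seen), had a log2 fold change of 1.15 (adjusted p = 0.04). Of 35 genes of G1/S and DNA replication, 29 fell, 2 rose and 4 did not pass, and the same 29 and 2 were counted adjusted over the list alone (median -2.32, camera adjusted p = 6.6e-13; adjusted p = 0.29 with an estimated correlation). CHAF1A, a chromatin assembly factor subunit, fell from 66.1 ± 4.76 to 8.54 ± 1.43 CPM, the replication helicase gene CDC45 from 38.7 ± 7.96 to 1.73 ± 1.13 CPM, and the cyclin gene CCNE2 from 26.6 ± 4.76 to 2.18 ± 1.06 CPM. TYMS, thymidylate synthase, and PCNA, the sliding clamp, rose by 1.23 and 1.57 (named after their values were seen).

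Of 20 genes of homologous recombination and Fanconi repair, 18 fell, 0 rose and 2 did not pass, and 19 fell adjusted over the list alone (median -2.37, camera adjusted p = 1.6e-11; adjusted p = 0.29 with an estimated correlation). FANCD2 fell from 26.5 ± 1.99 to 1.91 ± 0.842 CPM, XRCC2 from 24.2 ± 3.65 to 1.29 ± 0.756 CPM, and RAD54B from 28.6 ± 3.15 to 6.6 ± 0.889 CPM. Of 33 replication-dependent histones, which supply new chromatin in S phase, 21 fell and 12 did not pass, and 24 fell adjusted over the list alone (median -1.92, camera adjusted p = 1.0e-07; adjusted p = 0.43 with an estimated correlation). H1-5 fell from 655 ± 284 to 40.7 ± 23.6 CPM, H2BC12 from 144 ± 26.9 to 45.3 ± 6.97 CPM, and H3C13 from 49.5 ± 16.6 to 5.54 ± 1.13 CPM. Reads shared between histone paralogs could not be told from the table.

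The largest falls by the rule were the spindle gene ASPM (NM_018136, chromosome 1, 197053257 to 197115824; 442 ± 48.2 to 8.43 ± 4.95 CPM, log2 fold change -5.74, SE 0.43, adjusted p = 1.2e-05), FAM111B, the cytokinesis gene PRC1, CENPF, HJURP, BUB1, DEPDC1 and the mitotic motor gene KIF11, between -5.71 and -4.72 for the others. The largest rises included genes nearly silent in PBS. PDE4C, a cAMP phosphodiesterase (NM_001098819, chromosome 19, 18318771 to 18359010), rose from 2.1 ± 1.61 to 434 ± 291 CPM (log2 fold change 6.92, SE 1.02, adjusted p = 6.2e-04), and the small GTPase gene RRAD from 2.01 ± 1.74 to 408 ± 299 CPM. EPS8L2, the guidance cue gene NTN1, the antimicrobial ribonuclease gene RNASE7, the anchoring fibril collagen gene COL7A1 and TSPAN11 rose by 6.23 to 5.79. Dox replicate 1 was the lowest of its group for these genes, and the span of RNASE7 lies within NDRG2 on the opposite strand.

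**Figure D1:**
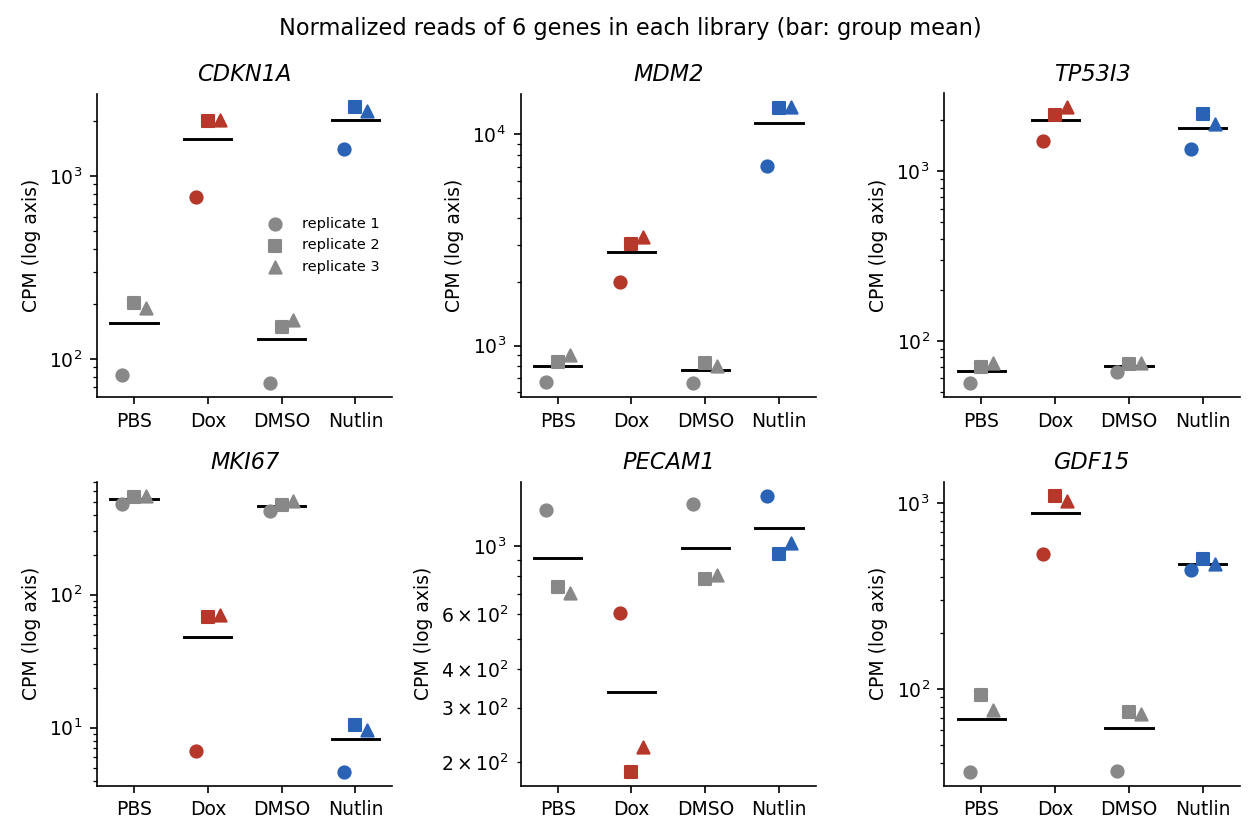
Level of CDKN1A, MDM2, TP53I3, MKI67, PECAM1 and GDF15 in each of the 12 libraries, in CPM on a log axis, by group; circles, squares and triangles are replicates 1, 2 and 3 and bars are group means. The mean of MDM2 was 803 CPM in PBS, 2760 in Dox, 764 in DMSO and 11300 in Nutlin, and PECAM1 was at 338 CPM in Dox against 1140 in Nutlin.

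Of 30 genes of endothelial identity, 11 fell, 1 rose and 18 did not pass, with the same counts adjusted over the list alone (median log2 fold change -0.71, camera adjusted p = 0.01; adjusted p = 0.49 with an estimated correlation). NOS3, the endothelial nitric oxide synthase gene (NM_000603, chromosome 7, 150688144 to 150711687), fell from 50.5 ± 19.4 to 11.9 ± 3.03 CPM (log2 fold change -1.93, SE 0.34, adjusted p = 0.0016). The junction gene ESAM fell from 115 ± 23.5 to 43.2 ± 10.3 CPM and the secreted vascular factor gene EGFL7 from 162 ± 7.64 to 29.6 ± 31.3 CPM. PECAM1 (NM_000442, chromosome 17, 62396777 to 62407083) had a log2 fold change of -1.58 (SE 0.44, adjusted p = 0.016), and adjusted p of 0.055 without PBS replicate 1, 0.074 without Dox replicate 2 and 0.068 without Dox replicate 3. The gene that rose was MMRN2, an endothelial matrix protein gene (0.90, named after its value was seen). In the same comparison 3 of 6 smooth muscle and pericyte markers rose, and 4 adjusted over the list alone, with a median of 1.07 (camera adjusted p = 0.057). Without replicate 1 of every group, 21 of 29 members of endothelial identity fell and 3 rose. In that fit 5379 of all 13573 genes tested fell and 5628 rose.

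Of 23 genes of cholesterol biosynthesis, 14 fell, 1 rose and 8 did not pass, and 16 fell adjusted over the list alone (median -1.26, camera adjusted p = 2.7e-05; adjusted p = 0.32 with an estimated correlation). The epoxidase gene SQLE fell from 134 ± 9.99 to 29.8 ± 1.82 CPM, and INSIG1, a sterol sensor, from 145 ± 10.2 to 16.2 ± 8.38 CPM. HSD17B7 was the member that rose (1.17, adjusted p = 0.032, named after its value was seen). Of 25 genes of ribosome biogenesis and RNA polymerase I, 10 fell, 2 rose and 13 did not pass, and 10 fell and 3 rose adjusted over the list alone (median -0.74, camera adjusted p = 0.022; adjusted p = 0.32 with an estimated correlation). The blocked fit counted 16 falling and 4 rising, and without replicate 1 of every group the list had an adjusted p of 0.076. UTP20 fell from 91.8 ± 11.8 to 37.8 ± 10.1 CPM, the pseudouridine synthase gene DKC1 from 126 ± 48.2 to 34.6 ± 11.8 CPM, and POLR1B from 92.6 ± 14.1 to 41.3 ± 11.8 CPM. The members that rose were POLR1C (0.71) and RRP12 (0.98), named after their values were seen.

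Of 27 genes of NF-kB and leukocyte adhesion, 14 rose, 1 fell and 12 did not pass, with the same counts adjusted over the list alone (median 1.34, camera adjusted p = 0.0059; adjusted p = 0.49 with an estimated correlation). The growth factor gene CSF3 rose from 1.36 ± 0.555 to 16.3 ± 5.5 CPM, the mitochondrial superoxide dismutase gene SOD2 from 52.7 ± 2.34 to 295 ± 107 CPM, and IRF1 from 7.37 ± 2.46 to 32.3 ± 6.1 CPM. The chemokine gene CXCL1 was the member that fell (-1.87, adjusted p = 0.006, named after its value was seen), and the blocked fit counted 4 falling. Of 31 interferon-stimulated genes, 10 rose, 2 fell and 19 did not pass, and 11 rose and 2 fell adjusted over the list alone (median 0.55, camera adjusted p = 0.015; adjusted p = 0.49 with an estimated correlation). The list had an adjusted p of 0.22 without Dox replicate 1 and of 0.062 without replicate 1 of every group, and the blocked fit counted 16 rising and 4 falling. ISG15 rose from 15 ± 1.35 to 128 ± 60.1 CPM, STAT2 from 45.8 ± 6.89 to 127 ± 13.3 CPM, and HERC5 from 0.426 ± 0.081 to 8.77 ± 1.61 CPM. IFI44 (-2.35) and IFIT5 (-0.77) were the members that fell, named after their values were seen.

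The list of PPARG and lipid handling did not pass by camera (median 0.36, adjusted p = 0.09) but passed upward by fry (adjusted p = 2.8e-04). Of its 25 members 11 rose, 4 fell and 10 did not pass, and 12 rose and 5 fell adjusted over the list alone. The desaturase gene SCD fell from 611 ± 217 to 64.2 ± 3.5 CPM (log2 fold change -3.16, SE 0.38, adjusted p = 1.8e-04), and HADHA was at 272 ± 146 and 279 ± 178 CPM. PPARG itself (NM_138712, chromosome 3, 12329349 to 12475855) was scarce and fell from 5.27 ± 1.73 to 2.56 ± 1.27 CPM (log2 fold change -0.83, SE 0.30, adjusted p = 0.048), in 2 of 3 pairs. The call of PPARG was weak and was lost in 14 of 20 settings. PPARG kept its call in the blocked limma fit and without replicate 1 of every group (limma adjusted p = 1.6e-06). Its adjusted p was 0.14 without PBS replicate 2 or 3, 0.15 and 0.17 without Dox replicates 2 and 3, and 0.47 and 0.51 without replicate 2 or 3 of every group. It was 0.14 with only the groups compared in the fit, 0.12 with voom, 0.066 with no filter, 0.053 with DESeq2 size factors, 0.061 and 0.062 with edgeR without and with the block, and 0.073 with the deposited scaling, and it rounded to 0.05 with a pseudocount of 4.

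Among the other stress and vascular lists, none passed with Dox by camera, and NRF2 and glutathione genes passed upward by fry (adjusted p = 4.5e-04). Immediate early and AP-1 genes had 7 of 20 rising and 1 falling (also adjusted over the list alone; median 0.68, camera adjusted p = 0.064), with an adjusted p of 0.021 (0.33 with an estimated correlation) and 11 rising in the blocked fit, of 0.013 without PBS replicate 2, 0.022 without PBS replicate 3 and 0.023 without Dox replicate 1. JUN and DUSP6 had log2 fold changes of -0.26 and -0.12. The unfolded protein and integrated stress response had 9 of 27 rising and 2 falling (median 0.30, camera adjusted p = 0.17; 12 and 6 in the blocked fit), with HSP90B1 at -0.48 and SLC7A11 at -0.50 (adjusted p = 0.0012 without Dox replicate 1). NRF2 and glutathione genes had 6 of 20 rising and 0 falling (median 0.04, camera adjusted p = 0.15; 8 and 3 in the blocked fit), with TXNRD1 at -0.93 (adjusted p = 0.13, 0.028 blocked and 4.6e-04 without Dox replicate 1) and PRDX1 at -0.37. Genes of BMP signaling and pulmonary vascular homeostasis had 8 of 27 rising and 4 falling (8 falling in the blocked fit; median -0.09 but mean 0.18 and an upward test, camera adjusted p = 0.83), with the caveolin gene CAV1 at -0.21 and APLN at -0.44. For these 4 lists the counts adjusted over the list alone were the same.

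Angiogenesis and tip cell genes had 5 of 22 rising and 1 falling, also adjusted over the list alone (median 0.31, camera adjusted p = 0.26), and 9 and 4 in the blocked fit. The tip cell gene ESM1 rose from 564 ± 39.6 to 2440 ± 1100 CPM (log2 fold change 2.02, SE 0.31, adjusted p = 8.1e-04). Genes of TGF-beta, matrix and mesenchymal transition had 3 of 27 rising and 6 falling, also adjusted over the list alone (median -0.09, camera adjusted p = 0.78, with fry's direction upward), and 6 and 8 in the blocked fit. Fibronectin, FN1, was at 9580 ± 5280 and 16500 ± 6140 CPM (log2 fold change 0.85, adjusted p = 0.23 and 0.0011 blocked). Genes of senescence-associated secretion had 8 of 29 rising and 3 falling, and 9 and 3 adjusted over the list alone (median 0.16, camera adjusted p = 0.43; 11 and 5 in the blocked fit). The collagenase gene MMP1 rose by 1.46 (adjusted p = 0.031, and 0.1, 0.087 and 0.063 without PBS replicate 2, PBS replicate 3 and Dox replicate 1). None of 42 ribosomal protein genes passed (median -0.31, camera adjusted p = 0.43). In the blocked fit 13 fell and 1 rose and the list had an adjusted p of 0.027 (0.59 with an estimated correlation), and it had 0.011 without Dox replicate 1. RPS6 and RPL5 had log2 fold changes of -0.60 and -1.29 (adjusted p = 0.41 and 0.4; 0.048 and 0.0031 blocked), and RPS6 had an adjusted p of 0.03 without Dox replicate 1.

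Of 6 smooth muscle and pericyte markers 3 rose, and 4 adjusted over the list alone (median 1.07, camera adjusted p = 0.057; 0.015, 0.022 and 0.044 without PBS replicate 1, Dox replicate 1 and Dox replicate 3). The smooth muscle actin gene ACTA2 (NM_001613, chromosome 10, 90694831 to 90751147) rose from 18.3 ± 2.8 to 205 ± 7.5 CPM (log2 fold change 3.43, SE 0.15, adjusted p = 6.7e-07), and shares 860 bp with FAS on the opposite strand. The pericyte gene RGS5 was at 232 ± 97.3 and 405 ± 76.6 CPM (adjusted p = 0.075; 7.3e-04 blocked and 0.027 without PBS replicate 1). Of 2 leukocyte markers 1 rose (median 1.92, camera adjusted p = 0.27; 0.046, 0.036, 0.032 and 0.0044 without PBS replicates 1, 2, 3 and Dox replicate 1). That marker was LAPTM5, a lysosomal gene, from 4.19 ± 3.07 to 64.5 ± 40.3 CPM (adjusted p = 0.0058), while CD68 had a log2 fold change of 0.24 (adjusted p = 0.42, and 0.033 without Dox replicate 1). Of 5 lymphatic endothelial markers 1 rose, RELN, by 1.10 (adjusted p = 0.028), but its adjusted p was between 0.055 and 0.11 without PBS replicate 2 or 3 or any of Dox replicates 1, 2 and 3. LYVE1 was at -1.33 (adjusted p = 0.52, blocked 0.032), and the blocked fit counted 3 lymphatic markers rising and 1 falling (list median 0.59, camera adjusted p = 0.5). None of 4 fibroblast markers passed (median 0.01, camera adjusted p = 0.83), with COL1A2 at 0.86 (adjusted p = 0.36, blocked 0.034) and FAP at 0.03, and 1 rose in the blocked fit. Of 4 lung epithelial markers 1 fell, the keratin gene KRT18 (-0.51, adjusted p = 0.035), with adjusted p of 0.057, 0.11, 0.11 and 0.066 without PBS replicates 2 and 3 and Dox replicates 2 and 3. KRT19 was at 0.34, and the list median was 0.01 with a downward test (camera adjusted p = 0.98; 1 rising and 1 falling in the blocked fit). For lymphatic, leukocyte and lung epithelial markers the counts adjusted over the list alone were the same.

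Across all genes, 98.4% of the 5031 calls had the same sign in all 3 same-numbered pairs. The number of calls depended on the libraries: 3317 without Dox replicate 2, 11007, 567 and 558 without replicate 1, 2 or 3 of every group, and 3190 with only the Dox and PBS libraries in the fit.

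The second comparison, Nutlin against DMSO, asked what p53 activation without a DNA-damaging drug does to these cells. Again p53 targets rose and cell cycle genes fell, while most endothelial identity genes did not pass the test. MDM2 rose from 764 ± 89.6 to 11300 ± 3660 CPM, TP53I3 from 71 ± 4.6 to 1800 ± 416 and CDKN1A from 129 ± 48.3 to 2010 ± 528. MKI67 fell from 467 ± 39.5 to 8.26 ± 3.15 CPM. In all, 728 genes rose and 795 fell, of 1523 past the threshold, and 439 and 516 of them by at least 2-fold. The blocked fit called 3390 genes, 1721 rising and 1669 falling, among them all 1523. Because each replicate number is in every group, the block leaves fold changes as they are, so their direction could not change.

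Of the 50 p53 activated targets, 39 rose, 0 fell and 11 did not pass, and 46 rose adjusted over the list alone (median log2 fold change 1.63, camera adjusted p = 5.6e-36). This call held with an estimated correlation (adjusted p = 0.035), as did that of G1/S and DNA replication, and those of the other 8 lists that passed were lost. MDM2 rose by a log2 fold change of 3.83 (SE 0.30, adjusted p = 2.4e-05), with 174941 to 290770 reads in the Nutlin libraries. TP53I3 rose by 4.62 (SE 0.22, adjusted p = 1.3e-06), FAS by 2.71 from 20.1 ± 1.85 to 137 ± 15.6 CPM (SE 0.14, adjusted p = 2.1e-06), and SPATA18, a gene of mitochondrial quality control, by 1.91 from 30.1 ± 3.23 to 115 ± 6.34 CPM. CDKN1A rose by 4.00 (SE 0.48, adjusted p = 3.6e-04) and GDF15 by 2.98 from 61.5 ± 22.2 to 469 ± 30.7 CPM (adjusted p = 8.0e-04).

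Of 27 apoptosis regulators, 4 rose, 0 fell and 23 did not pass, and 7 rose and 3 fell adjusted over the list alone (median 0.42, camera adjusted p = 0.0083; adjusted p = 0.28 with an estimated correlation). The blocked fit counted 11 rising and 4 falling. PMAIP1 rose from 51.2 ± 3.09 to 126 ± 25.4 CPM and BBC3 from 11.7 ± 4.31 to 43.7 ± 13.9 CPM, as did BCL2L1, which encodes the anti-apoptotic BCL-XL, from 176 ± 43.8 to 452 ± 45.3 CPM.

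All 35 genes of G2/M and mitosis fell, also adjusted over the list alone (median -4.69, camera adjusted p = 1.5e-45; adjusted p = 0.055 with an estimated correlation). CENPF fell from 629 ± 40.1 to 15.3 ± 1.62 CPM (log2 fold change -5.28, SE 0.24, adjusted p = 1.1e-06), NUF2 by a log2 fold change of -5.13 and the checkpoint gene BUB1B by -5.33. Of 35 genes of G1/S and DNA replication, 32 fell and 3 did not pass, and 33 fell adjusted over the list alone (median -2.55, camera adjusted p = 2.2e-32; adjusted p = 0.035 with an estimated correlation). CDC45 fell from 34.9 ± 6.8 to 0.824 ± 0.0656 CPM, the helicase gene MCM5 from 111 ± 11.6 to 18.9 ± 0.942 CPM and CHAF1A from 62.5 ± 6.9 to 11 ± 0.472 CPM. Of 20 genes of homologous recombination and Fanconi repair, 18 fell and 2 did not pass, and 19 fell adjusted over the list alone (median -2.42, camera adjusted p = 7.9e-23; adjusted p = 0.055 with an estimated correlation, 0.035 blocked). FANCD2, XRCC2 and RAD51AP1 had log2 fold changes of -3.30, -3.59 and -4.35. Of 33 replication-dependent histones 29 fell and 4 did not pass, and 33 fell adjusted over the list alone (mean log2 fold change -3.31, camera adjusted p = 1.5e-25; adjusted p = 0.11 with an estimated correlation, 0.047 blocked). H2BC12 fell from 118 ± 20.4 to 17.5 ± 2.61 CPM, H3C13 from 30.6 ± 6.74 to 0.932 ± 0.955 CPM and H1-5 from 571 ± 245 to 7.86 ± 3.47 CPM.

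By the rule, the largest falls were ASPM (395 ± 14.9 to 4.1 ± 1.9 CPM; log2 fold change -6.36, SE 0.43, adjusted p = 8.8e-06), the topoisomerase gene TOP2A (393 ± 3.64 to 4.45 ± 1.87 CPM), H3C2, DLGAP5, KIF20A, H2AC14, H1-5 and MKI67, the last at -5.72 (SE 0.69, adjusted p = 3.9e-04). The largest rises again included genes nearly silent in the vehicle. DRAXIN, a guidance cue gene, rose from 0.218 ± 0.191 to 110 ± 82.7 CPM (log2 fold change 5.91, SE 1.02, adjusted p = 0.0036). The chloride channel regulator gene CLCA2 rose from 0.119 ± 0.103 to 69.9 ± 48.2 CPM, with 0 to 3 reads in the DMSO libraries, and the adhesion gene NECTIN4 from 0.237 ± 0.269 to 46.8 ± 23 CPM. RRAD, EPS8L2, TP53I3 and the polarity gene PARD6G rose by 5.47 to 4.17. The atypical cadherin gene FAT1 rose by 4.66 (adjusted p = 0.02), with adjusted p of 0.059, 0.058 and 0.071 without DMSO replicates 1, 2 and 3 and of 0.094 and 0.093 without Nutlin replicates 2 and 3.

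Of 25 genes of ribosome biogenesis and RNA polymerase I, 6 fell, 0 rose and 19 did not pass, and 8 fell adjusted over the list alone (median -0.66, camera adjusted p = 3.3e-05; adjusted p = 0.055 with an estimated correlation). The blocked fit counted 14 falling. The nucleolin gene NCL fell from 1470 ± 436 to 479 ± 9.88 CPM, NOLC1 from 245 ± 30.4 to 112 ± 4.51 CPM and NOP56 from 212 ± 27.1 to 100 ± 30.7 CPM. Of 23 genes of cholesterol biosynthesis, 5 fell, 0 rose and 18 did not pass, also adjusted over the list alone (median -0.58, camera adjusted p = 0.001; adjusted p = 0.37 with an estimated correlation; 7 falling and 1 rising in the blocked fit). EBP fell from 47.2 ± 7.33 to 19.5 ± 0.927 CPM and SQLE from 120 ± 24.8 to 62.5 ± 8.09 CPM.

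Of 27 genes of NF-kB and leukocyte adhesion, 4 rose, 0 fell and 23 did not pass, and 6 rose adjusted over the list alone (median 0.67, camera adjusted p = 0.001; adjusted p = 0.44 with an estimated correlation). The blocked fit counted 12 rising and 1 falling. SELE, the E-selectin gene, rose from 1.78 ± 0.806 to 14.5 ± 6.29 CPM, TRAF1 from 3.04 ± 0.649 to 19.6 ± 7.41 CPM, and the NF-kB inhibitor gene NFKBIA from 89.9 ± 27.1 to 249 ± 68.5 CPM (adjusted p = 0.01, and 0.056 and 0.051 without Nutlin replicates 2 and 3). The remaining riser was ICAM1, an adhesion receptor gene (1.96, named after its value was seen). Of 20 immediate early and AP-1 genes, 2 rose and 18 did not pass, and 1 rose adjusted over the list alone (median 0.39, camera adjusted p = 0.038; adjusted p = 0.62 with an estimated correlation; 5 rising in the blocked fit). The list had adjusted p of 0.32, 0.072 and 0.093 without DMSO replicate 1, Nutlin replicate 2 and Nutlin replicate 3. DUSP5, a phosphatase gene, rose by 1.22 (adjusted p = 0.021, and between 0.059 and 0.087 without DMSO replicate 1 or 2 or Nutlin replicate 2 or 3). JUNB rose by 1.32 at an adjusted p that rounds to 0.05, and lost its call, at 0.08 to 0.14, without any 1 of the 6 DMSO and Nutlin libraries, and in 14 of 20 settings in all. IER5 was at 0.73 (adjusted p = 0.073, blocked 0.014).

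**Figure D2:**
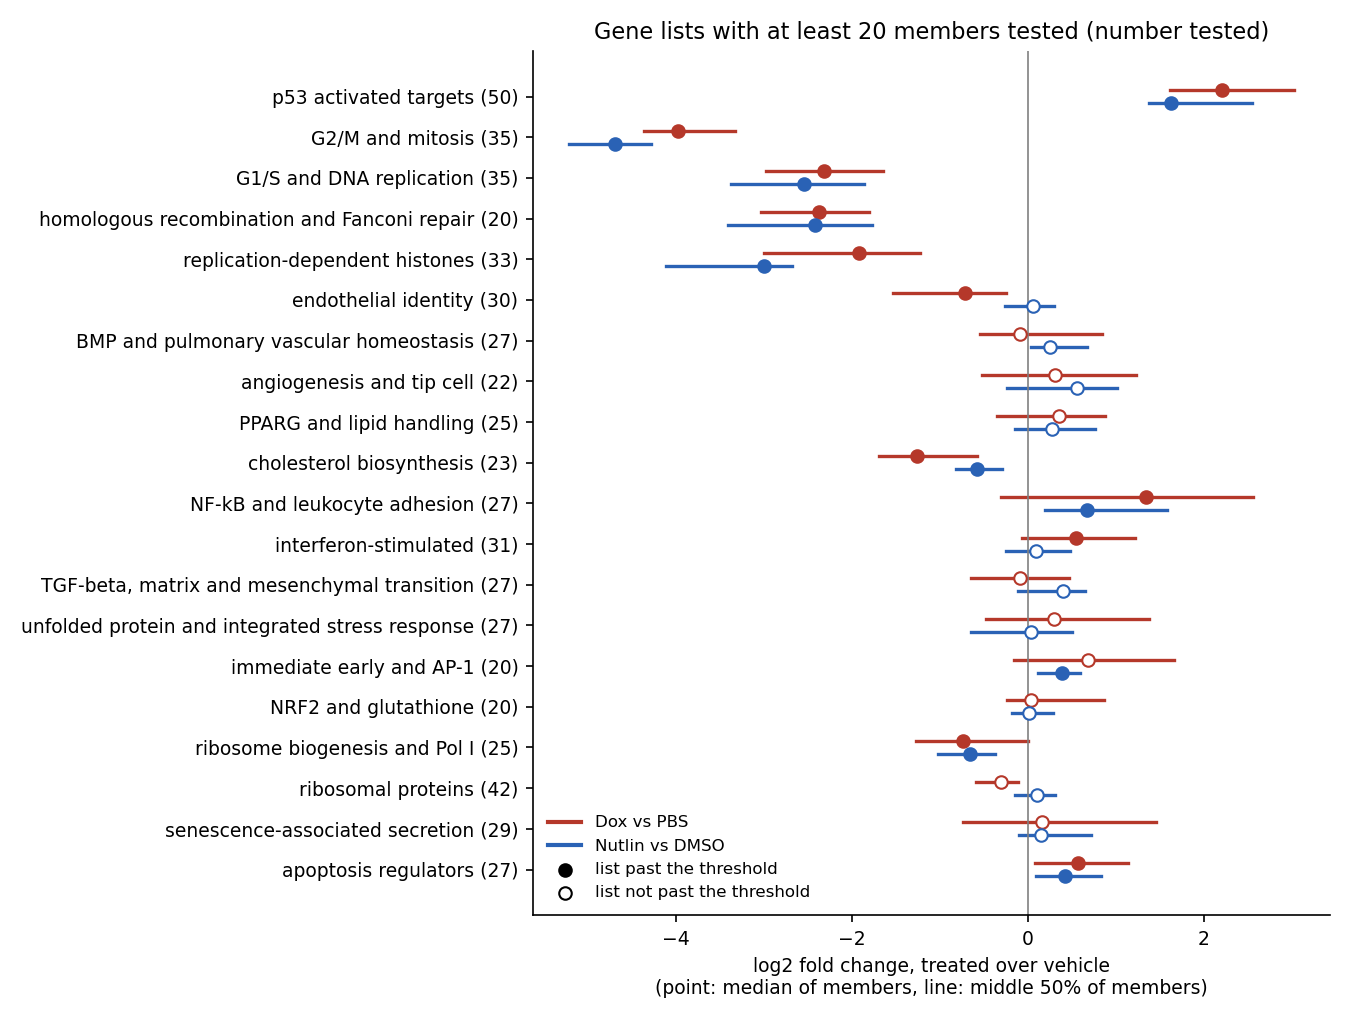
Log2 fold change of the members of the 20 lists with at least 20 members tested, with Dox against PBS in red and Nutlin against DMSO in blue; points are medians, lines span the middle 50% of the members, and filled points are lists past the threshold with the preset correlation. The median of the p53 activated targets was 2.21 with Dox and 1.63 with Nutlin, and that of G2/M and mitosis -3.98 and -4.69.

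Endothelial identity did not pass with Nutlin (median 0.06 but mean -0.02, camera adjusted p = 0.59), and of 30 members 1 rose, 0 fell and 29 did not pass, also adjusted over the list alone (2 and 1 in the blocked fit). The member was CDH5, the VE-cadherin gene, from 1240 ± 126 to 2510 ± 377 CPM (log2 fold change 1.01, SE 0.23, adjusted p = 0.018). Its adjusted p lay between 0.053 and 0.099 without DMSO replicate 2 or 3 or any of Nutlin replicates 1, 2 and 3. Without replicate 1 of every group, 12 of 29 members of endothelial identity fell with Nutlin and 7 rose (median -0.07). In that fit 3887 of all 13573 genes tested fell and 4011 rose. PECAM1 was at 981 ± 327 and 1140 ± 274 CPM (log2 fold change 0.24, adjusted p = 0.81) and MMRN1 at 4770 ± 2320 and 3060 ± 1480 CPM (adjusted p = 0.62). PPARG was at 5.46 ± 1.38 and 4.73 ± 0.484 CPM (log2 fold change -0.15, adjusted p = 0.82). Its list had 6 of 25 rising and 2 falling, and 7 and 3 adjusted over the list alone (median 0.28, camera adjusted p = 0.088, fry adjusted p = 0.0059). SCD was at -1.17 (adjusted p = 0.074, with 0.0039 blocked and 0.01 without DMSO replicate 1) and HADHA at 0.07.

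Genes of BMP signaling and pulmonary vascular homeostasis had 2 of 27 rising and 1 falling, and 4 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.077); the blocked fit gave 8 and 2 and an adjusted p of 0.025 (0.22 with an estimated correlation). CAV1 rose from 1320 ± 55.5 to 2060 ± 140 CPM (adjusted p = 0.032), with adjusted p of 0.076 to 0.15 without DMSO replicate 1, 2 or 3 or Nutlin replicate 2 or 3, and APLN was at 0.59 (adjusted p = 0.55). Angiogenesis and tip cell genes had 3 of 22 rising and 1 falling, and 4 and 1 adjusted over the list alone (median 0.56, camera adjusted p = 0.075). The blocked fit gave 8 and 1 and an adjusted p of 0.018 (0.22 with an estimated correlation), and the list had 0.026, 0.013 and 0.023 without DMSO replicate 1, Nutlin replicate 2 and Nutlin replicate 3. ESM1 rose by 1.14 (adjusted p = 0.041, and 0.1 to 0.17 without DMSO replicate 1, 2 or 3 or Nutlin replicate 2 or 3). Genes of TGF-beta, matrix and mesenchymal transition had 3 of 27 rising and 0 falling, also adjusted over the list alone (median 0.40, camera adjusted p = 0.072, 0.018 blocked with 10 rising and 1 falling but 0.22 blocked with an estimated correlation, and 0.026 without DMSO replicate 1). FN1 was at 0.74 (adjusted p = 0.45, blocked 0.0055).

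The remaining lists did not pass with Nutlin by camera, and senescence-associated secretion passed upward by fry (adjusted p = 0.046). Senescence-associated secretion had 6 of 29 rising and 2 falling, also adjusted over the list alone (median 0.15, camera adjusted p = 0.23), with MMP1 at 0.68. Interferon-stimulated genes had 1 of 31 rising, and 0 adjusted over the list alone (median 0.09, camera adjusted p = 0.59; 3 and 3 in the blocked fit), with IFI27 at 0.55 and SAMD9L at 0.09. The unfolded protein and integrated stress response had 1 of 27 rising and 3 falling, also adjusted over the list alone (median 0.04 but mean -0.04 and a downward test, camera adjusted p = 0.59; 2 and 9 in the blocked fit), with HSP90B1 at -0.93 (adjusted p = 0.18, blocked 0.031) and SLC7A11 at -0.09. NRF2 and glutathione genes had 2 of 20 rising, also adjusted over the list alone (median 0.01, camera adjusted p = 0.48; 3 rising and 1 falling in the blocked fit), with TXNRD1 at -0.55 and PRDX1 at -0.83 (adjusted p = 0.54, blocked 0.045). None of 42 ribosomal protein genes passed (median 0.11, camera adjusted p = 0.62, and 0.018 without DMSO replicate 1), and 2 rose in the blocked fit, with RPS6 at 0.11 and RPL5 at -0.36.

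Of the markers of other cell types, ACTA2 was the 1 of 6 smooth muscle and pericyte markers that rose, from 20.6 ± 2.84 to 93.1 ± 4.6 CPM (log2 fold change 2.13, SE 0.15, adjusted p = 1.1e-05; list median 0.38, camera adjusted p = 0.15). RGS5 was at 0.56 (adjusted p = 0.37, blocked 0.016). None of the 4 fibroblast (median -0.04, camera adjusted p = 0.66), 5 lymphatic endothelial (median 0.29, 0.51), 2 leukocyte (median 1.08, 0.3) and 4 lung epithelial markers (median 0.20, 0.77) passed. The blocked fit counted 2 smooth muscle markers and 1 leukocyte marker rising, and 1 lung epithelial marker rising and 1 falling. COL1A2 was at 0.14, FAP at 0.01, LYVE1 at -0.16, RELN at 0.51 and CD68 at 0.27. LAPTM5 was at 1.88 (adjusted p = 0.18, blocked 2.9e-04), KRT18 at -0.44 (adjusted p = 0.13, blocked 0.042) and KRT19 at 0.99 (adjusted p = 0.12; 0.012 blocked and 0.0025 without Nutlin replicate 1).

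All of the 1523 calls (100%) had the same sign in all 3 same-numbered pairs. Their number was 815, 834, 830 and 844 without DMSO replicate 2, DMSO replicate 3, Nutlin replicate 2 and Nutlin replicate 3, was 7898, 143 and 190 without replicate 1, 2 or 3 of every group, and DESeq2 called 2334.

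The third comparison set the responses side by side, to ask which changes DNA damage and direct p53 activation share. Of the genes called, 549 rose in both (140 expected, odds ratio 16.2, p = 2.8e-255, Fisher's exact test) and 646 fell in both (150 expected, odds ratio 24.8). These were 75.4% of the genes that rose and 81.3% of the genes that fell with Nutlin. Of 1208 genes called in both, 1195 (98.9%) had the same sign, and the responses have no control library in common. Across genes, which are not independent replicates, the fold changes correlated at 0.71 over all genes and 0.94 over those called in both. The shared calls numbered 2507 in the blocked fit and 2033 without Dox replicate 1, and 132 and 163 without replicate 2 or 3 of every group. They numbered 710, 724, 710 and 728 without DMSO replicate 2, DMSO replicate 3, Nutlin replicate 2 and Nutlin replicate 3.

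The test of the difference of responses, Nutlin minus Dox, called 296 genes. Most had changed with Dox alone by the threshold: 119 rose with Dox and did not pass with Nutlin, and 110 fell with Dox and did not pass with Nutlin. In 23 genes that rose in both the rise was smaller with Nutlin, and 10 genes fell with Dox and rose with Nutlin. MDM2 rose more with Nutlin (difference of log2 fold changes 2.07, SE 0.43, adjusted p = 0.041), and PMAIP1, the other p53 target past the threshold (named after its value was seen), rose less (-1.82, adjusted p = 0.018). CDKN1A differed by 0.69 (adjusted p = 0.63, blocked 0.045) and GDF15 by -0.74 (adjusted p = 0.52). PECAM1 differed by 1.81 (adjusted p = 0.13; 0.0055 blocked and 0.0046 without Dox replicate 1), MKI67 by -1.76 (adjusted p = 0.34, and 3.9e-04 without Dox replicate 1) and PPARG by 0.68 (adjusted p = 0.4).

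The largest differences towards Nutlin were in LINC01235, the metalloprotease gene ADAMTS18, SELE, the cadherin gene CDH4, NEGR1 and SKP2, a ubiquitin ligase subunit gene (2.36 to 3.35). SELE was at 1.46 ± 0.522 CPM in Dox and 14.5 ± 6.29 in Nutlin libraries, and SKP2 at 5.45 ± 2.6 and 30.5 ± 2.46. The largest towards Dox were in RNASE7, the carnosine synthase gene CARNS1, COL7A1, the glutaminase gene GLS2, KLC3 and ESPN, an actin-bundling protein gene (-5.90 to -4.40). RNASE7 was at 173 ± 132 CPM in Dox and 0.211 ± 0.198 in Nutlin libraries, GLS2 at 119 ± 86.8 and 1.57 ± 1.13, and COL7A1 at 100 ± 53 and 2.02 ± 1.52.

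**Figure D3:**
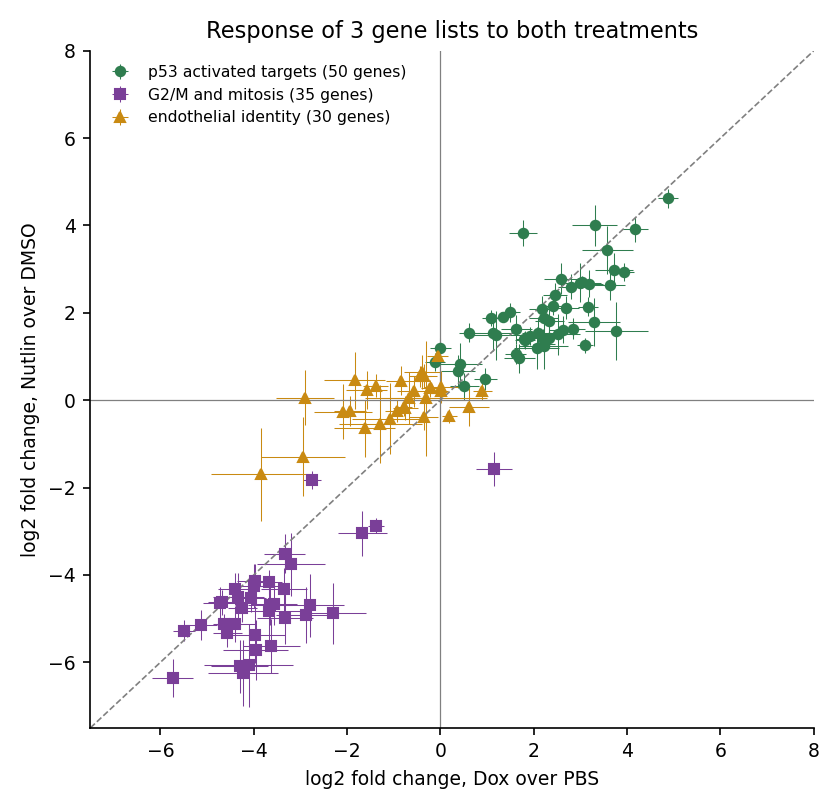
Log2 fold change with Dox against PBS (horizontal) and Nutlin against DMSO (vertical) for 50 p53 activated targets, 35 genes of G2/M and mitosis and 30 of endothelial identity; each point is a gene, bars are standard errors and the dashed line marks equal responses. MDM2 lies at 1.76 and 3.83, PMAIP1 at 3.09 and 1.26, and PECAM1 at -1.58 and 0.24.

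By list, the difference was negative for G2/M and mitosis (median -0.76, camera adjusted p = 0.0013, 2 of 35 members past the threshold, both lower, PTTG1 and CKS2, named after their values were seen), histones (-1.27, 6.7e-05, 0 of 33), interferon-stimulated genes (-0.74, 0.021, 3 lower, 5 adjusted over the list alone) and the unfolded protein and integrated stress response (-0.57, 0.021, 2 lower, 3 adjusted over the list alone). It was positive for endothelial identity (0.75, 5.7e-04, 1 higher, 12 blocked) and cholesterol biosynthesis (0.80, 0.0055, 2 higher, 5 adjusted over the list alone). With an estimated correlation these 6 lists had adjusted p of 0.78 to 0.8. In the blocked fit the members past the threshold were 4 lower and 1 higher for G2/M, 15 lower for histones, 7 lower for interferon-stimulated genes, 7 lower for the unfolded protein response and 7 higher for cholesterol biosynthesis. That fit gave 10 lists, adding p53 targets (median -0.36, adjusted p = 0.059 to 0.034), G1/S (-0.46, 0.053 to 0.025), TGF-beta (0.40, 0.085 to 0.02) and ribosomal proteins (0.45, 0.21 to 9.6e-04), each at 0.6 in that fit with an estimated correlation. Members past the threshold in it were 7 higher and 8 lower for p53 targets, 1 and 6 for G1/S, 10 and 2 for TGF-beta and 5 and 0 for ribosomal proteins. G2/M had an adjusted p of 0.051 without Nutlin replicate 1. Interferon-stimulated genes had 0.058, 0.51, 0.089 and 0.051 without PBS replicate 2, Dox replicate 1, DMSO replicate 1 and Nutlin replicate 3. The unfolded protein response had 0.052 to 0.21 without PBS replicate 1, Dox replicate 2 or 3, DMSO replicate 2 or 3, or Nutlin replicate 1.

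The other lists did not pass for the difference, with adjusted p of 0.34 for homologous recombination, 0.35 for BMP, 0.97 for angiogenesis, 0.38 for PPARG, 0.34 for NF-kB, 0.47 for immediate early, 0.22 for NRF2 and 0.82 for ribosome biogenesis. They were 0.97 for secretion, 0.15 for apoptosis, 0.11 for smooth muscle, 0.66 for fibroblast, 0.88 for lymphatic (median -0.10 but mean 0.11), 0.66 for leukocyte and 0.82 for lung epithelial genes. Members past the threshold numbered 1 higher for BMP, 1 higher and 2 lower for NF-kB, 2 lower for secretion and for apoptosis, and 1 lower for TGF-beta, immediate early, NRF2 and smooth muscle. Adjusted over the list alone they numbered 3 higher and 1 lower for BMP, 1 and 4 for NF-kB, 5 and 2 for TGF-beta, 2 and 3 for secretion, 1 and 1 for PPARG, and 0 and 2 for G1/S, NRF2 and smooth muscle, and were the same for the others. In the blocked fit they numbered 6 higher and 2 lower for BMP, 4 and 5 for NF-kB, 3 and 5 for secretion, 2 and 5 for apoptosis, and 1 and 4 for immediate early and for NRF2. They numbered 1 and 2 for angiogenesis, for PPARG and for ribosome biogenesis, and 0 and 1 for homologous recombination and for leukocyte markers. Without Dox replicate 1 the lists of p53 targets, G1/S, ribosomal proteins, smooth muscle and leukocyte markers passed as well, and 10 lists did in all.

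The count of 296 genes changed when libraries were left out of the fit without the block. It was 0 without PBS replicate 2 or 3, Dox replicate 2 or 3, DMSO replicate 2 or 3 or Nutlin replicate 2. It was 1 without DMSO replicate 1 or Nutlin replicate 3, 4060 without Dox replicate 1 and 8843 without replicate 1 of every group. The blocked fit with all libraries called 2156. Leaving out a single library also left the replicate numbers uneven between groups, which the fit without the block does not model. No blocked fit was run with a library left out, so the losses cannot be laid to single libraries rather than to this imbalance.

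The vehicles, DMSO against PBS, were compared as a background for both drugs. limma called 0 genes, with 62 at an unadjusted p under 0.05, and edgeR called 0, with 94. The blocked limma and edgeR fits called 0, with 222 and 273, and DESeq2 and voom called 0. Without any difference, a well calibrated test would on average put a share of 0.05 of the genes tested under that p. All these counts at an unadjusted p fell short of that share, furthest without the block. The fits without the block count differences between replicate numbers as error. The 0 calls therefore do not show that the vehicles are alike. CDKN1A, MDM2, GDF15, MKI67 and PECAM1 had log2 fold changes of -0.26, -0.07, -0.12, -0.16 and 0.11, and PPARG of 0.06, all at an adjusted p of 1. Without replicate 1 of every group, 11 genes passed. With the preset correlation 5 lists passed: TGF-beta (median -0.24, adjusted p = 9.9e-06), p53 targets (-0.11, 0.011), the unfolded protein response (-0.14, 0.011), immediate early (0.13, 0.011) and interferon-stimulated genes (0.08, 0.018). No member of any list passed, all 5 had an adjusted p of 0.78 with an estimated correlation and of 1 with fry, and the other 20 lists had adjusted p of 0.056 to 0.95. In NF-kB, PPARG, apoptosis, smooth muscle and leukocyte genes, whose medians were between -0.03 and 0.09, the median, the mean and the test did not share a direction. The blocked fit gave 8 lists, adding histones (0.008), angiogenesis (0.017) and ribosome biogenesis (0.017), which had 0.58, 0.46 and 0.46 in that fit with an estimated correlation. The calls of lists changed when single libraries were left out of the fit without the block. That also left the replicate numbers uneven between the vehicles, and replicate 1 stood apart. Ribosomal protein genes had a median log2 level of 9.08, 7.31 and 7.23 in PBS replicates 1, 2 and 3. The changes of list calls therefore cannot be told apart from this imbalance. TGF-beta had an adjusted p of 0.24 without PBS replicate 1, and immediate early genes had 0.59, 0.7 and 0.88 without PBS replicate 1, DMSO replicate 2 and DMSO replicate 3. Without PBS replicate 2, PBS replicate 3 and DMSO replicate 1, p53 targets had 0.11, 0.083 and 0.18, interferon-stimulated genes 0.68, 0.34 and 0.31, and the unfolded protein response 0.25, 0.34 and 0.91. The number of lists past the threshold was 9 without PBS replicate 1, DMSO replicate 2 or DMSO replicate 3, 3 without PBS replicate 2 and 2 without PBS replicate 3. Ribosomal protein genes passed in either direction, with medians of 0.56, -0.58, 0.30 and 0.32 without PBS replicate 1 and DMSO replicates 1, 2 and 3, and histones with -0.62, 0.39, -0.38 and -0.49.

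Because doxorubicin acts on topoisomerase II along DNA, its response was compared across genes by their span. Long genes fell more often with Dox: of the quintile of genes with the longest spans, 86.1 to 2320 kb, 703 fell and 360 rose, and of the quintile with the shortest, 0.061 to 8.47 kb, 360 fell and 535 rose. Median log2 fold changes were -0.22 and 0.06. With Nutlin the medians were 0.04 and 0.03, with 100 falling and 168 rising among the longest. Spearman's rho of fold change with span, across genes that are not independent replicates, was -0.122 with Dox (-0.0989, -0.113 and -0.126 in the 3 pairs), -0.00131 with Nutlin (-0.0684, 0.0269 and 0.0485), and 0.168 for the difference. For the vehicles it was -0.0216, and -0.0873, 0.106 and 0.00245 in the pairs, so that the Dox values in pairs were near the size of the widest vehicle pairs. Without PBS replicate 1 or Dox replicate 3 the Dox value was -0.0861 or -0.0954.

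**Figure D4:**
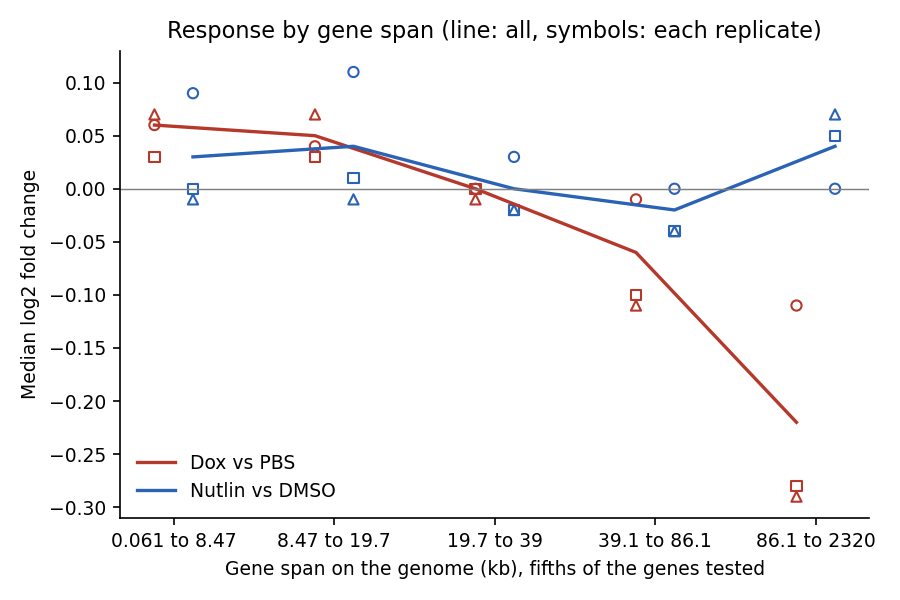
Median log2 fold change of the genes in each quintile of gene span, in kb, for Dox against PBS and Nutlin against DMSO; lines join the medians over all libraries and symbols are the 3 same-numbered pairs. With Dox the median ran from 0.06 in the shortest to -0.22 in the longest quintile, and with Nutlin it was between -0.02 and 0.04 in every quintile.

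The authors' DESeq2 table listed 5104 genes, 3061 with a positive and 2043 with a negative log2 ratio, and the edgeR table listed 3618, with 2315 and 1303. Of these, 4733 and 3002 were tested here. Across those genes the authors' ratios correlated with the limma fold changes at 0.91 (both tables) for Dox against PBS and at 0.79 and 0.80 for Nutlin against DMSO. These correlations did not separate the possible sides, so log2 ratios of mean CPM were compared for every way to set groups on 2 sides, chosen after the tables were seen. Dox and Nutlin libraries together against PBS and DMSO libraries together came closest, with a median absolute difference from the authors' ratios of 0.02 (DESeq2 table) and 0.03 (edgeR table) and a correlation of 1.00 in both. Both drugs against 1 vehicle were at 0.06 to 0.08, and no other way was under 0.25. Of the genes in the DESeq2 table, 3702 were called here with Dox and 1390 with Nutlin, all with the sign of the table, and for the edgeR table these counts were 2674 and 1238. The authors chose these genes on the same libraries, so the counts are not independent evidence.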

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

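The contrast for the difference of responses, the gene lists and the rule for named genes were chosen before the data were examined. The limma test was not, since it replaced the planned edgeR test because the deposited values are scaled. What singled out every result below is the test of the difference between the response to Nutlin (against DMSO) and the response to Dox (against PBS), with n = 3 libraries per group.

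In all, 296 genes differed in response, with 142 more positive and 154 more negative with Nutlin. They all had the same sign of difference in all 3 same-numbered pairs (100%), and the blocked fit called 2156 genes, among them all 296. Their direction could not change, since the block leaves fold changes as they are. edgeR on recovered reads called 233 genes, 212 of them among the 296. The 10 splits of the libraries are too few for a share under 0.05. The real value was 296 and the highest of the others 0, and 1 of 10 splits, the real one, gave as many. Every other split mixed Dox and Nutlin libraries within a group, so that differences between the drugs counted as error there. Their 0 genes therefore do not speak against chance.

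Of single genes, the difference of log2 fold changes was most positive in LINC01235 (3.35, SE 0.68), ADAMTS18 (2.99, SE 0.64), SELE (2.72, SE 0.47), CDH4 (2.55, SE 0.42), NEGR1 (2.40, SE 0.34) and SKP2 (2.36, SE 0.46). All but SELE fell with Dox and did not pass with Nutlin, and SELE rose with Nutlin and did not pass with Dox. The difference was most negative in RNASE7 (-5.90, SE 1.10), CARNS1 (-4.97, SE 0.79), COL7A1 (-4.80, SE 0.73), GLS2 (-4.65, SE 1.03), KLC3 (-4.65, SE 1.00) and ESPN (-4.40, SE 0.99), which all rose with Dox and did not pass with Nutlin. MDM2, which both drugs raised, differed by 2.07 (SE 0.43) towards Nutlin. Adjusted p of these 13 genes lay between 0.018 and 0.049, and all 13 calls were lost without PBS replicate 2 or 3, Dox replicate 2 or 3, any DMSO library, or Nutlin replicate 2 or 3, when that of MDM2 was between 0.086 and 0.12. Those fits had no block. With all libraries, 7 of the 13 calls were lost with edgeR on recovered reads, 10 with voom, 6 with no filter, 5 with the deposited scaling and 1 with DESeq2. The blocked limma fit kept all 13.

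Of gene lists, the median difference was -0.76 for G2/M and mitosis, -1.27 for replication-dependent histones, 0.75 for endothelial identity, 0.80 for cholesterol biosynthesis, -0.74 for interferon-stimulated genes and -0.57 for the unfolded protein and integrated stress response. These 6 passed with the preset correlation and none with an estimated one (adjusted p = 0.78 to 0.8) or with fry's test of direction (0.26 to 0.46), while fry's mixed test, of members changed either way, passed for endothelial identity (0.025), cholesterol biosynthesis (0.014) and interferon-stimulated genes (0.014). Of the 50 p53 activated targets, 2 differed in response past the threshold, MDM2 and PMAIP1, and 15 did in the blocked fit. Beforehand, 5 or more had been set as the mark of a difference and 0 as that of none. The reported fit therefore left open whether the targets that rise differ between the drugs. The blocked fit, which allows for the shared replicate numbers, was past the mark of a difference, with 7 higher and 8 lower. That mark had been set for a fit without the block.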

How the results depend on the processing

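Among the settings given here, edgeR on recovered reads, pseudocounts of 0.25 and 4, the scaling as deposited, the lists without a whole replicate, and the overlap and p53 targets without a whole replicate or with voom, size factors or only the groups compared were chosen after seeing the data. Of results past the threshold in either fit, leaving out libraries reversed 5 lists of DMSO against PBS and no other. Medians of lists past it in neither fit also turned. The median of immediate early genes, 0.13, became -0.12 to 0.36 (negative without PBS replicate 1 or DMSO replicate 3). The medians of interferon-stimulated genes (0.08), the unfolded protein response (-0.14), histones (-0.19) and ribosomal proteins (0.02) turned without DMSO replicate 1, and became -0.07 to 0.22, -0.35 to 0.03, -0.62 to 0.39 and -0.58 to 0.56. The last 2 lists had not passed with all libraries in the fit without the block, and histones did pass in the blocked fit (camera adjusted p = 0.008). No gene called in the reported fits was called in the opposite direction under any setting. Of the named genes, 48 of 81 with Dox, 32 of 78 with Nutlin, 0 of 19 in the difference and 7 of 7 in DMSO against PBS kept their side of the threshold under every setting, and of the 25 lists 8, 10, 13 and 11 did. For Dox the 5031 genes became 3190 when only the groups compared were fitted, 3106 with a log2 fold change of at least 1, and 558 to 11007 with libraries left out. DESeq2, voom, edgeR, DESeq2 size factors, no filter, both pseudocounts and the deposited scaling gave 4532 to 5953. For Nutlin the 1523 genes became 2334 with DESeq2, 955 with a log2 fold change of at least 1, and 143 to 7898 with libraries left out. The deposited scaling gave 1402, of which 36.7% rose, against 47.8%. For the difference the 296 genes became 1354 with DESeq2, 115 with voom, 160 with the deposited scaling (35.6% positive, against 48%), and 0 to 8843 with libraries left out. For DMSO against PBS, 0 genes became 0 to 11 with libraries left out. The overlap of 1195 genes became 772 with a log2 fold change of at least 1 and 132 to 5688 with libraries left out, lowest without replicate 2 of every group. Lists past the threshold went from 11 to 0 for Dox, from 10 to 2 for Nutlin, from 6 to 0 for the difference and from 5 to 0 for DMSO against PBS with an estimated correlation. With fry's test of direction Dox and Nutlin had 14 lists each, and the difference and DMSO against PBS had 0. With Dox fry added the PPARG, NRF2 and smooth muscle lists. With Nutlin it added the PPARG, BMP, TGF-beta, secretion and smooth muscle lists and lost immediate early genes. With libraries left out, camera gave 4 to 10 lists for the difference and 2 to 9 for DMSO against PBS. The p53 targets that rose, 43 with Dox and 39 with Nutlin, were 25 to 48 and 12 to 50 with libraries left out, lowest without replicate 2 or 3 of every group, and were 41 to 46 and 38 to 48 under the other settings. The rho of the Dox response with gene span, -0.122, was -0.142 to -0.0861 with single libraries left out, and crossed the bound of -0.1 without PBS replicate 1 or Dox replicate 3. Leaving out replicate 1 of every group raised the counts of genes. That left replicates 2 and 3, whose log levels correlated at 0.996 to 0.997, against 0.882 to 0.941 with replicate 1. The fit without the block counts such differences between replicates as error. What else raised the counts was not tested.

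With the replicate block, Nutlin against DMSO had 3390 genes (3427 with edgeR), the difference 2156 (2046 with edgeR), and the overlap 2507 (2548 with edgeR), while Dox against PBS had 7378 and DMSO against PBS 0. The block kept every reported gene call and gave 10 lists for the difference and 8 for DMSO against PBS. It leaves the limma fold changes as they are, so the direction of these calls could not change. The reported fit recovered 6% of simulated 2-fold changes and the blocked fit 54%. The simulation changed 100 genes per fold, far fewer than passed with Dox or Nutlin. An adjusted p is harder to pass when fewer genes change, so these shares do not give the share recovered in those comparisons. Genes not called here can still include changes of that size.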

Other observations

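The test of sequencing depth for the genes with reads in Dox libraries was chosen after the result was seen, as were the genes named here, and the other tests were written down before it.

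The list of PPARG and lipid handling did not pass with either drug by camera. It passed upward by fry (adjusted p = 2.8e-04 with Dox and 0.0059 with Nutlin). Of its 25 members, 10 with Dox and 17 with Nutlin did not pass. Among those that did, ABCA1, the cholesterol efflux transporter gene, rose from 3.11 ± 0.861 to 89.7 ± 52.6 CPM with Dox and by a log2 fold change of 3.62 (SE 0.54) with Nutlin. ANGPTL4, which encodes an inhibitor of lipoprotein lipase, rose by 3.05 and 2.05 (SE 0.32), the lipid droplet gene PLIN2 by 1.58 and 0.76 (SE 0.14), and the fatty acid oxidation gene ACADVL by 2.20 and 1.06 (SE 0.24), while the fatty acid binding protein gene FABP5 fell (-1.54 and -1.68, SE 0.28). None of the 25 members of the list passed in the difference of responses.

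The list of BMP signaling and pulmonary vascular homeostasis did not pass with Dox, and 15 of its 27 members did not pass. Among those that did, the transcription factor genes ID2 (3.48, SE 0.88) and KLF4 (2.25, SE 0.33) and the inhibitory SMAD7 (2.28, SE 0.75) rose, and SMAD6 (-1.52, SE 0.21), KLF2 (-1.80, SE 0.45) and EDN1, the endothelin gene (-1.46, SE 0.32), fell. BMPR2, the BMP receptor gene, was at 0.49 with Dox and 0.83 with Nutlin (adjusted p = 0.16 and 0.065; 0.0044 and 5.5e-04 blocked). Of stress genes, ATF3 rose by 5.09 with Dox (SE 0.59) and was at 1.10 with Nutlin (adjusted p = 0.29), a difference of -4.00 (SE 0.84, adjusted p = 0.041), and DDIT3 was at 3.76 and 0.60 (adjusted p of the difference 0.083). Some p53 targets rose with Nutlin and did not pass with Dox. CCNG1, the cyclin G1 gene, was at -0.00 with Dox and 1.20 with Nutlin, and TNFRSF10D, a decoy receptor gene, at -0.11 and 0.87. Their differences did not pass (adjusted p = 0.071 and 0.094), but did in the blocked fit (0.0036 and 0.017).

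Long genes fell more than short ones with Dox and not with Nutlin (rho -0.122 and -0.00131), below Nutlin in all 3 pairs. Abundance is argued against as the whole reason, since within groups of genes of like mean CPM the mean rho was -0.103 (SE 0.0149), below the -0.05 that abundance would have allowed by more than 2 SE. The mean was past the bound of -0.1 set beforehand for the opposite outcome by less than its SE, and the use of 2 SE was chosen after the value was seen. Lost RNA integrity and transcript lifetime were not tested, the trend was weak, and the vehicles gave -0.0873 in 1 pair.

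More genes had reads in the Dox libraries, and thinned to 12916924 reads each these held 14667, 16694 and 16851 genes, against 13924 to 14575 with either vehicle. Depth is argued against, since after thinning each Dox library exceeded the higher vehicle library of its number by at least 688 genes. Genomic DNA or another even background is argued against as the whole reason, since among genes silent in all 6 vehicle libraries the reads per kb of olfactory receptor genes were 0.0377 of those of other genes (95% bootstrap interval 0.0207 to 0.0605), where an even background would give 0.5 to 2. Of the 5702 others, 438 had over 10 reads in Dox libraries against 25 with Nutlin, but olfactory receptor genes also had more, 0.0687 reads per kb against 0.0153 (9.14% against 2.36% with reads), so a small added background is not excluded. Reads spilling past the ends of genes or from introns, and RNA of other cells, were not tested and stay open.

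The Dox response was smaller in replicate 1, with 2447 genes over 2-fold against 4351 and 4446 in replicates 2 and 3 and a slope of 0.56 across genes. With Nutlin the slope was also below 1, at 0.71, but replicate 1 had more such genes (2149, against 1567 and 1662), so the slope alone does not show a smaller response, and G2/M genes fell more with Dox in replicate 1 (median -4.92, against -3.21 and -3.29). Depth is argued against for the number of genes, since thinning replicate 1 left 2504 genes over 2-fold. Thinning moved the slope by -0.0003, but the slope cannot decide on depth. Counting noise added to replicate 1 alone, the response being fitted, leaves the slope nearly unchanged whatever the cause. A raised p53 target level at the start was not seen in the list as a whole. The targets differed in PBS replicate 1 by a median of -0.21, and a median that was not higher had been set beforehand as the outcome against this cause. Single targets went both ways, with an SD of 0.67 and 20 of 50 higher. By that spread, a criterion chosen after the value was seen, the cause stays open. The passage of the cells may contribute, but it cannot be told apart from a batch of culture or sequencing, because replicate 1 is at once the lowest passage and the deepest in all 4 groups.

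For the other comparisons the 10 splits of 6 libraries are likewise too few for a share under 0.05. The real values were 5031 for Dox and 1523 for Nutlin, the highest of the other splits 0 for both, and 1 of 10 splits, the real one, gave as many. The other splits mixed treated and vehicle libraries within a group, so that the drug effect counted as error there. Their 0 genes therefore do not speak against chance either. For DMSO against PBS all 10 splits gave 0 genes, with limma as in the report (62 at an unadjusted p under 0.05, and 0 genes with edgeR). Of the 10 splits 4 part all 3 same-numbered pairs, the real one among them.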
